A study of Arabidopsis thaliana with 8 samples.

How the data were processed

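The series holds 8 RNA-seq libraries from 2-week-old Arabidopsis plants grown in long days, labelled as leaf material: Col-0 and lsm8-1 in soil at 20 °C, in soil after 24 h at 4 °C, on plates of 0.5X GM medium, and on plates after 10 h with 150 mM NaCl. Per the labels, total RNA was extracted with TRIzol, treated with DNase and cleaned on columns, and libraries followed a standard Illumina preparation. Whether a library pooled several plants, and whether it kept the strand of the RNA, is not stated. Each group has 1 library. All 8 root markers reached 5 CPM on GM against 1 of 8 at 20 °C, so the plate libraries were not taken to be free of roots.

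Per the file headers, each deposited table lists the number of uniquely placed reads (raw count), the reads scaled to feature length and library total (RPKM), the length of the feature and the share of its length covered (coverage). The deposited counts were whole numbers from 1 up that summed to the total in the header, so a feature not listed was taken as 0. The deposited RPKM values equalled the count divided by the length and the header total, as the unit defines and as tested on the files, and were not used further. Coverage was not used. It passed 100% for 2 features in a NaCl table and 1 in the other. Reads were placed on TAIR10 per the submitters' processing notes, while the aligner, the counting tool and their versions are not given in the sources used here. The annotation at hand was TAIR10.1, so chromosomes are given without coordinates.

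The cold experiment was deposited per gene (21570, 21848, 21511 and 21733 genes listed) and the salt experiment per transcript model (29007, 29541, 29509 and 30229 models listed). The counts of the models of a locus were summed here to 1 count per gene. Of 26547 loci with any read, 5144 have several models in the salt tables, and these hold far fewer reads there than in the cold tables, so that reads shared by models appear not to have been counted. Levels of such loci are therefore not comparable between the experiments, and every ratio is taken within 1 experiment. Within the salt experiment a shift in model use could still change the summed count of such a locus. Ratios of these loci on plates may hold this besides a change of level.

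The total count ranged from 33.4 M to 45.9 M reads (M, 1e6 reads), and the 10 highest genes took 6.47% to 13.1% of them. A count of 0 was given a floor of 3 counts of the library, 0.0654 to 0.0897 CPM by the total and 0.0672 to 0.0899 CPM after TMM scaling, which all printed CPM and bounds use. Ratios between 2 libraries have exact Clopper-Pearson 95% intervals from the counts, and shares have Wilson 95% intervals. These cover counting error only, since reads without molecular identifiers are not independent molecules.

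Counts were scaled by TMM (factors 0.756 to 0.845 in the cold and 1.16 to 1.32 in the salt experiment) with edgeR 4.0.16 in R 4.3.3. Genes with 1 CPM or more in at least 2 libraries were tested, 20228 in all. An additive model with 1 coefficient per condition and 1 for genotype was fitted to the 8 libraries (3 residual degrees of freedom) by the quasi-likelihood method of edgeR, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. It gave 3 effects: lsm8-1 against Col-0 over the 4 conditions, 4 °C against 20 °C over both genotypes, and NaCl against GM over both genotypes. The spread it uses holds any difference in response between the genotypes as well as noise. In simulated data of the same design with 200 changed genes, 70% were recovered at 2-fold and 96% at 4-fold.

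Differences between 2 single libraries (4 of genotype, 4 of stress, and the difference between the genotypes in each stress response) are log2 ratios of TMM-scaled CPM with a pseudocount of 1. They have no test. Genes were ranked on these log2 ratios. Values printed as folds or as ratios with an interval are ratios of TMM-scaled CPM without a pseudocount. At low counts they are larger than the log2 ratios imply. Genes at 5 CPM or more in at least 1 of the libraries compared were counted when the ratio reached 2-fold. In simulated pairs with the common dispersion of 0.0316, 97% (20 °C) and 97.5% (GM) of genes changed 4-fold passed this count.

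Before the data were examined, 20 lists of 246 genes were fixed: LSM family, cold-responsive genes (CBF regulon and early cold), ABA and osmotic stress, ion transport under salt, light harvesting and RuBisCO small subunit, circadian clock, flowering time, salicylic acid defence, jasmonate, splicing factors, heat shock and chaperones, flavonoid and anthocyanin, aliphatic glucosinolate, iron deficiency, senescence and sugar starvation, cell division, root markers, flower markers, seed markers and reference genes. All 246 had a read. The intronless genes of the annotation (2799 tested) formed 1 more list. For the 3 fitted effects, lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated from the residuals. The estimated correlation ended every call: 5 lists for genotype, 6 for cold and 10 for salt with the preset value, and 0 with the estimated one. Fry of limma, a rotation test of whether the members of a list move one way, was run beside camera and does not compare the list with other genes. It called 0, 9 and 10 of the 21 lists for genotype, cold and salt. For single-library comparisons a list's median log2 ratio was placed among 10000 random lists of as many genes matched on mean expression in 20 bins. For the differences in response, random lists matched on the mean response to the stress were drawn as well. In a test with 200 random lists, 5.5% fell outside the central 95%. This test could not show the effect of members that vary together, which random genes do not copy. The estimated correlation for genotype was 0.94 for aliphatic glucosinolate, 0.69 for salicylic acid, 0.66 for light harvesting, 0.58 for iron deficiency and 0.55 for ABA. It was near 0 for others, such as splicing factors (-0.03). Percentiles are therefore descriptions and overstate how unusual a correlated list is. The intronless list was given no percentile.

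The genes named were fixed by a rule: the LSM family, the 10 highest and 10 lowest per fitted effect among genes past the threshold that moved the same way in every pair and had a mean of at least 5 CPM, the 5 highest and 5 lowest per single-library comparison at 10 CPM or more, the 8 highest and 8 lowest per difference in response, and up to 4 members per list. Organelle genes were left out of the named genes and given as a group. BGLU23 and PHT1;1 belong to the root-marker list. Genes named in the closing section for mitochondrial stress and for transcript models were chosen after the data were seen.

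The alternatives tried were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors or library totals in place of TMM, no filter or one of 5 CPM on low counts, each experiment alone, leaving out the pair of libraries of each condition in turn, no condition term, a pseudocount of 0.1, and floors of 1 and 20 CPM. Fits that leave out a pair have fewer residual degrees of freedom than the full fit, so a call can be lost through lower power. Fits of each experiment alone have fewer still. Added after the data were seen were fits and counts on genes with 1 transcript model and on genes with reads in both experiments. Values were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Splicing within genes was not measured from reads, since raw reads were not analysed here. The salt tables alone hold counts per transcript model.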

Results

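RNA from 2-week-old Arabidopsis plants, labelled as leaf material, was sequenced in the accession Col-0 and in lsm8-1, a mutant of LSM8, the subunit that defines the nuclear LSM2-8 ring on the U6 small nuclear RNA of the spliceosome. The labels give 4 conditions in 2 experiments. In the cold experiment plants grew in soil at 20 °C and were sampled there or after 24 h at 4 °C, under light of 90 and 40 µmol m-2 s-1. In the salt experiment plants grew on plates of 0.5X GM medium and were sampled there or after 10 h with 150 mM NaCl, under light of 90 µmol m-2 s-1. Each genotype had 1 library per condition, 8 in all, so no difference within a condition could be set against a spread between replicates. The total count, in units of 1e6 reads (M), was 44.2 M, 45.9 M, 45.9 M and 45.9 M reads in the cold experiment (Col-0 and lsm8-1 at 20 °C, then both at 4 °C). It was 33.4 M, 33.6 M, 34.0 M and 34.0 M in the salt experiment (Col-0 and lsm8-1 on GM, then both with NaCl). A count of 0 allows up to 3 counts, which is 0.0672 to 0.0899 CPM (counts per 1e6 reads, TMM-scaled) over the libraries. Intervals and floors cover counting error only. Root markers were far higher on plates than in soil. BGLU23 (AT3G09260, a beta-glucosidase of root ER bodies) stood at 5666 and 3600 CPM on GM (Col-0, lsm8-1) against 144 and 92.4 CPM at 20 °C in soil. PHT1;1 (AT5G43350, a root phosphate transporter) stood at 200 and 177 CPM on GM and had no read at 20 °C. All 8 root markers reached 5 CPM on GM and 1 of 8 did at 20 °C, so it is open whether the plate libraries held roots besides leaves. Values on plates have to be read with this in mind, among them those of iron-deficiency, root-marker, light-harvesting and aliphatic glucosinolate genes. Reads of organelle genes made up 1.52%, 1.13%, 1.11% and 1.07% of the cold libraries, in the order above. They made up 0.0816% (0.0806 to 0.0825, Wilson 95% confidence interval) and 0.188% (0.186 to 0.189) of Col-0 and lsm8-1 on GM. With NaCl the shares were 0.0733% (0.0724 to 0.0742) and 0.318% (0.316 to 0.320).

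The level of LSM8 (AT1G65700, chromosome 1) was lower in lsm8-1 in all 4 pairs of libraries, and each lsm8-1 library held reads of the locus. Raw reads were not analysed, so where these reads lie relative to the mutation is not known. LSM8 had 578 reads in Col-0 and 206 in lsm8-1 at 20 °C, 1816 and 821 at 4 °C, 269 and 51 on GM, and 208 and 29 with NaCl. The ratio of lsm8-1 to Col-0 was 0.321 (0.273 to 0.377, exact Clopper-Pearson 95% interval), 0.439 (0.404 to 0.477), 0.207 (0.150 to 0.280) and 0.152 (0.0993 to 0.225) in that order. In the additive fit of genotype and condition over the 8 libraries the genotype effect on LSM8 was -1.85 (log2, SE 0.24) with an adjusted p of 0.0219 (edgeR quasi-likelihood, Benjamini-Hochberg). The adjusted p became 0.103 without the 20 °C pair and 0.0626 without the GM pair. Of the 11 LSM family genes measured, which also hold the LSM1 genes of the cytoplasmic ring, LSM8 was the one past the threshold. Adjusted over the list alone, 5 members were higher and 1 lower in lsm8-1, and the set test (camera) gave an adjusted p of 0.413. The family median was 0.36 (log2) at 20 °C, 0.31 at 4 °C, 0.12 on GM and 0.11 with NaCl, the last of which turned to just under 0 when libraries were scaled by their totals. LSM8 rose with cold (1.74, SE 0.32, adjusted p = 0.00431), as did LSM2 (AT1G03330, 0.50), LSM4 (AT5G27720, 0.46) and LSM6A (AT3G59810, 0.58). No LSM gene passed the threshold for salt (0 of 11 by edgeR quasi-likelihood, 0 at an unadjusted p under 0.05 and 0 by DESeq2), where LSM8 had -0.56 (SE 0.35, adjusted p = 0.262).

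**Figure D1:**
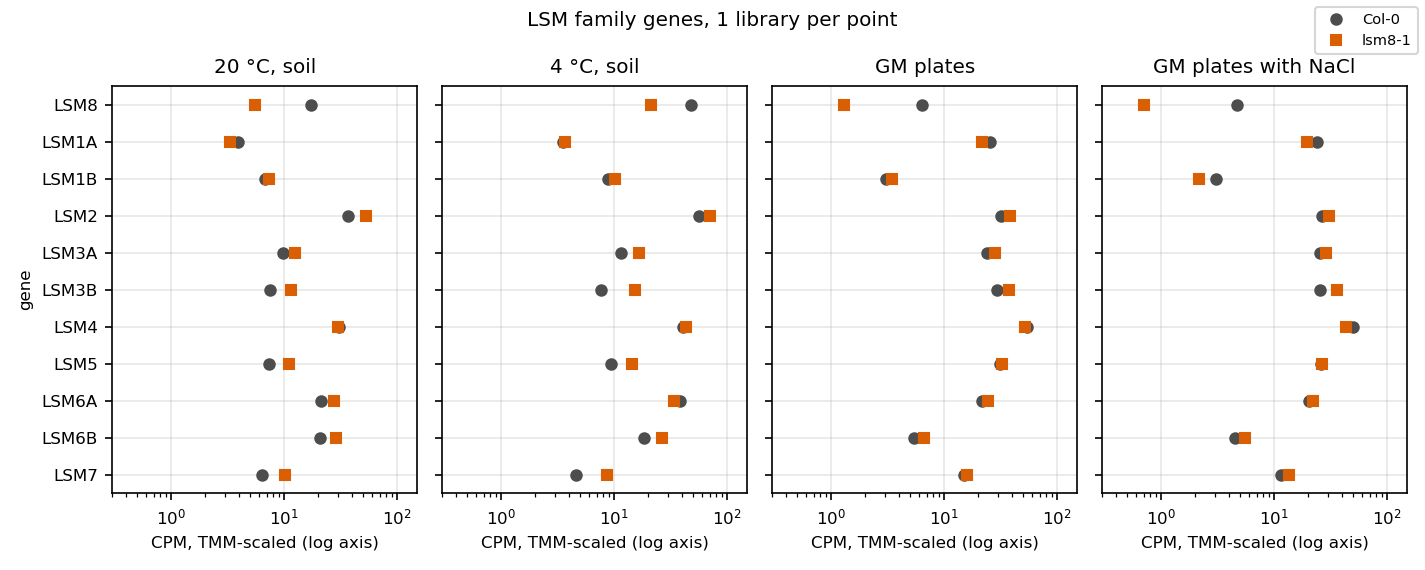
TMM-scaled CPM (log axis) of the 11 LSM family genes in Col-0 (circles) and lsm8-1 (squares), 1 library per point, in the 4 conditions. LSM8 stands at 17.3 and 5.56 CPM (Col-0, lsm8-1) at 20 °C, 48.3 and 21.2 at 4 °C, 6.31 and 1.31 on GM, and 4.66 and 0.708 with NaCl.

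The first question was which transcripts differ between lsm8-1 and Col-0 whatever the environment. The MATE efflux genes AT2G04050 and AT2G04070 (chromosome 2) had genotype effects of 4.84 (log2, SE 0.71) and 4.61 (SE 0.52), and NDB4 (AT2G20800, an alternative NAD(P)H dehydrogenase of mitochondria) had 3.38 (SE 0.38). SRO3 (AT1G70440, a relative of the stress regulator RCD1) had 4.1 (SE 0.37), and QQS (AT3G30720, an orphan gene that affects starch content) had 4.97 (SE 0.34). QQS stood at 0.959 and 26.8 CPM at 20 °C, 0.717 and 8.80 at 4 °C, 0.915 and 40.1 on GM and 0.358 and 22.2 with NaCl (Col-0, lsm8-1). The retroelement SADHU3-2 (AT3G42658) had 4.37 (SE 0.19) and went from 1.34 to 25.9 CPM on GM. In the edgeR quasi-likelihood test these 6 genes had Benjamini-Hochberg adjusted p of 0.0321, 0.0154, 0.0154, 0.00865, 0.00258 and 0.000577, and all 6 were higher in 4 of 4 pairs. The uncharacterized gene AT4G04170 (chromosome 4, adjusted p = 0.000869) had no read in 3 of the Col-0 libraries and 0.0895 CPM with NaCl, against 0.540, 0.103, 33.5 and 30.4 CPM in lsm8-1. The P-loop NTPase genes AT2G18193 (4.79, SE 0.83) and AT2G18190 (3.85, SE 0.65) and the F-box gene AT5G55150 (3.50, SE 0.37) completed the 10 highest, with adjusted p of 0.0474, 0.0451 and 0.0151. AT2G04050 and AT2G04070, like AT2G18190 and AT2G18193, lie close together and are related in sequence. The counts are of uniquely placed reads, so reads that match both genes of such a pair alike may be missing. SRO3 overlaps a gene on the opposite strand, and the strand of the reads is not stated.

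In this fit fewer genes were lower in lsm8-1 than higher, and the lowest changed less than the highest. The balance depended on the fit, with 703 higher and 801 lower in the cold experiment alone. MLP328 (AT2G01520, a major latex protein relative) had -3.04 (log2, SE 0.31), from 220 to 21.2 CPM on GM and from 70.5 to 8.86 with NaCl, and was near 0.1 CPM in soil in both genotypes. AT3G58550 (a lipid-transfer-like protein) had -2.90 (SE 0.41), the MATE gene AT5G38030 -1.97 (SE 0.25), and the hydrolase gene AT1G47480 -1.59 (SE 0.19). PIP5K5 (AT2G41210, a phosphatidylinositol phosphate kinase) had -1.35 (SE 0.17), and RPL3B (AT1G61580, a ribosomal protein) had -1.22 (SE 0.20). Their adjusted p were 0.0146, 0.0294, 0.0207, 0.0187, 0.0205 and 0.0418 (edgeR quasi-likelihood, Benjamini-Hochberg), with each gene lower in 4 of 4 pairs. AT5G44568 (-1.48), the MYB-like gene AT1G13300 (-1.31) and AT2G07774 (-1.3) were the other lower genes named, besides LSM8. AT3G58550 and RPL3B overlap genes on the opposite strand, and the call of MLP328 was lost with DESeq2 (adjusted p = 0.126).

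In all, 221 of the 20228 genes tested passed the threshold for genotype, 153 higher and 68 lower in lsm8-1, and 3769 had an unadjusted p under 0.05. Of the 221, 202 went the same way in all 4 pairs, and 13 had no read in the cold experiment. Without the 20 °C, 4 °C, GM or NaCl pair the count was 34, 51, 29 or 101, of which 30, 40, 29 and 70 were higher. These fits also have fewer residual degrees of freedom, so the fall cannot be laid to the pair left out alone. DESeq2 called 1405 genes (766 higher, 639 lower). The cold experiment alone gave 1504 (703 higher, 801 lower) and the salt experiment alone 184 (140 higher, 44 lower). Fits of 1 experiment have fewer residual degrees of freedom than those without a pair. Their counts rest on a weaker estimate of the spread. A fit with no condition term gave 0 (98 at an unadjusted p under 0.05, edgeR quasi-likelihood). QQS, SADHU3-2 and SRO3 passed without each pair in turn, and AT4G04170 and AT5G55150 passed in the left-out fits that tested them. The other 15 of the 20 named genes lost the call in at least 1 of these fits. Every pair compares lsm8-1 with Col-0, so these fits cannot separate the allele from other differences between the lines. For AT2G04050 and AT2G18193 the call held only without the NaCl pair (adjusted p = 0.00234 and 0.00128). AT1G13300, AT2G07774 and AT5G44568 lost it in every left-out fit. In simulated data this test recovered 70% of 200 genes changed 2-fold with 14 false calls, and 96% of those changed 4-fold with 15 false calls.

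**Figure D2:**
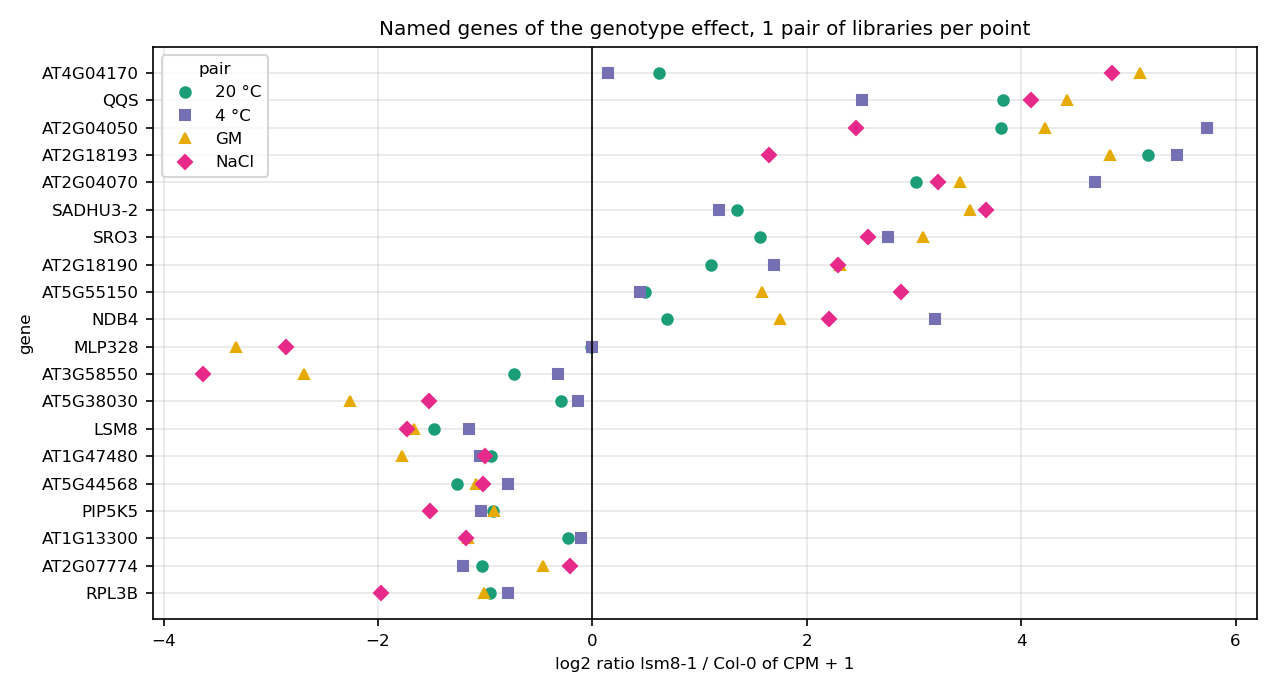
Log2 ratio of CPM + 1 between lsm8-1 and Col-0 in each of the 4 pairs of libraries (points) for the 20 genes named for the genotype effect. The ratios of QQS lie at 3.83 (20 °C), 2.51 (4 °C), 4.42 (GM) and 4.09 (NaCl).

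Among the gene lists, the iron-deficiency list stood out in lsm8-1: 6 of its 9 members were higher, and all 9 adjusted over the list alone. The members past the threshold were the transcription factors BHLH38 (AT3G56970, 3.24, SE 0.46), BHLH100 (AT2G41240, 3.0, SE 0.33), BHLH101 (AT5G04150, 2.60, SE 0.29) and BHLH39 (AT3G56980, 1.84, SE 0.28). The others were the iron-regulated peptide genes IMA2 (AT1G47395, 2.61, SE 0.30) and IMA1 (AT1G47400, 2.43, SE 0.39), near-identical neighbours. Their adjusted p were 0.0294, 0.0151, 0.0154, 0.0378, 0.017 and 0.041 (edgeR quasi-likelihood, Benjamini-Hochberg). BHLH38 stood at 0.719 and 1.97 CPM at 20 °C, 0.0797 and 0.516 at 4 °C, 6.64 and 62.8 on GM, and 0.694 and 17.1 with NaCl. The list was called by camera (adjusted p = 3.97e-21), with adjusted p = 0.498 with an estimated correlation. Without the 20 °C, 4 °C, GM or NaCl pair, 2, 4, 0 or 4 members passed (edgeR quasi-likelihood), and all 9 had an unadjusted p under 0.05 in each of these fits. The list median was 0.59, 0.43, 2.36 and 1.42 (log2) at 20 °C, 4 °C, on GM and with NaCl, with 3, 3, 9 and 7 of 9 members at 5 CPM or more, where the root-marker median was 0.00, 0.03, -0.16 and 0.43.

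Light harvesting and RuBisCO small subunit genes had 1 member of 20 past the threshold, LHCB3 (AT5G54270, an antenna protein of photosystem II, 1.02, SE 0.15, adjusted p = 0.0294 by edgeR quasi-likelihood with Benjamini-Hochberg). It passed only without the 20 °C pair among the left-out fits. Adjusted over the list alone, 9 members were higher. The list median was -0.03 at 20 °C, where 11 of 20 members were lower, 0.34 at 4 °C, 0.84 on GM and 0.78 with NaCl. These are single libraries, and whether the difference varied with the condition was not tested. Nor was a different share of leaf tissue in the plate libraries. Camera gave this list 1.42e-06, with adjusted p = 0.823 with an estimated correlation. Of the 17 salicylic acid defence genes 2 were higher, also adjusted over the list alone, and both were expressed mainly in soil: PR1 (AT2G14610, a pathogenesis-related protein, 3.14, SE 0.30, adjusted p = 0.00993) and PR2 (AT3G57260, a glucanase, 1.11, SE 0.17, adjusted p = 0.0341). PR1 stood at 4.31 and 26.2 CPM at 20 °C and 2.5 and 31.2 at 4 °C, and PR2 at 19.2 and 48.0, then 67.8 and 150. On plates both were under 1 CPM. PR1 lost its call without the 4 °C pair (0.0713), PR2 without any of the 20 °C, 4 °C and NaCl pairs (0.181, 0.160 and 0.0597). The list median was 0.50 at 20 °C, 0.67 at 4 °C and 0.16 with NaCl, and went the other way on GM (-0.20, 13 of 17 members lower, percentile 4.22). Camera called the list with adjusted p = 7.04e-04, with adjusted p = 0.857 with an estimated correlation. Aliphatic glucosinolate (0 of 11) and flavonoid and anthocyanin (0 of 14) genes had no member past the threshold, nor adjusted over the list alone (edgeR quasi-likelihood). At an unadjusted p under 0.05 there were 4 and 2, and by DESeq2 2 and 0. Their medians were higher on plates and lower at 4 °C: 0.22, -0.35, 1.23 and 1.45, and 0.12, -0.10, 0.39 and 1.23 (20 °C, 4 °C, GM, NaCl). Camera gave them 0.00252 and 0.0111, with adjusted p = 0.857 and 0.823 with an estimated correlation.

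No other list passed camera for genotype. GI (AT1G22770, GIGANTEA, a clock and flowering regulator) was the 1 of 17 clock genes past the threshold (0.92, SE 0.11, adjusted p = 0.0174 by edgeR quasi-likelihood with Benjamini-Hochberg), at 13.1 and 24.5 CPM at 20 °C, 93.5 and 164 at 4 °C, 53.8 and 120 on GM, and 83.6 and 144 with NaCl. Its call held without the NaCl pair and was lost without each of the others (0.0882, 0.0544 and 0.0720). None of the 21 splicing factor genes passed, 1 adjusted over the list alone. STA1 (AT4G03430, a PRP6-like splicing factor) had 0.63 (SE 0.13, adjusted p = 0.0701). Of the cold-responsive genes 0 of 17 passed and 1 adjusted over the list alone, and of the ABA and osmotic stress genes 0 of 23 and 2, both lower. No member passed among ion transport under salt (7), flowering time (10 tested), jasmonate (13), heat shock and chaperones (11), senescence and sugar starvation (5), cell division (10), root markers (8), flower markers (3), seed markers (2) and reference genes (9). Of the 164 members of all lists with 0 past the threshold by edgeR, 26 had an unadjusted p under 0.05 and DESeq2 called 11. Fry, a set test that does not compare a list with other genes, called none of the 21 lists for genotype (lowest adjusted p 0.176). Of 2799 intronless genes tested 26 were higher and 3 lower (35 and 7 adjusted over the list alone), and camera gave 0.956. Their median was -0.05 at 20 °C, -0.03 at 4 °C, 0.03 on GM and 0.17 with NaCl (1871 higher, 923 lower), against 0.06, 0.03, 0.00 and -0.03 for genes with an intron. The difference in salt response was 0.14 against -0.02, with no replicate check.

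At 20 °C in soil, the P-loop NTPase gene AT2G18193 was 95.3-fold higher (61.6 to 156) and AT5G51440 (HSP23.5, a mitochondrial small heat shock protein) 24.3-fold (19.0 to 31.6), from 1.98 to 48.1 CPM. AT5G35935 was 185-fold higher (72.1 to 682), QQS 28.0-fold (19.7 to 41.2), and AT4G12735, with no read in Col-0 and 22.3 CPM in lsm8-1, at least 248-fold higher than the floor of 3 counts (0.0899 CPM). Folds in this and later paragraphs have no pseudocount, while genes were ranked on log2 ratios with a pseudocount of 1. The lowest were GRP9 (AT2G05440, a glycine-rich protein, 24.5 to 4.05 CPM), AT3G17050 (26.1 to 5.86), GSTU13 (AT1G27130, a glutathione transferase, 300 to 96.5), XTH24 (AT4G30270, a cell wall xyloglucan enzyme, 339 to 111) and LAC8 (AT5G01040, a laccase, 13.2 to 3.67). The salicylic acid list had a median of 0.50 (log2), higher than every matched random list, and the flowering-time list 0.30 (percentile 98.5). In the latter MAF5 (AT5G65080, a MADS-box floral repressor) went from 1.29 to 14.7 CPM. Here and below, random lists do not copy how members of a list vary together, so the percentiles are descriptions only. In all, 175 of 14244 genes at 5 CPM or more differed at least 2-fold, 112 higher and 63 lower. These differences had no replicate check, and genes simulated without change gave 80 such differences under the fitted dispersion and 0 under counting noise alone.

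After 24 h at 4 °C, the 5 highest were 2 MATE genes, AT2G18193, AT4G12735 and UGT74E2 (AT1G05680, a glucosyltransferase of indole-butyric acid), which went from 3.14 to 79.0 CPM, 25.2-fold (21.0 to 30.6). AT2G04050 was 121-fold higher (84.0 to 181), AT2G04070 213-fold (90.8 to 656), AT2G18193 73.8-fold (56.5 to 98.5) and AT4G12735 62.6-fold (44.0 to 92.4). PDF1.2A (AT5G44420, a defensin) was lower, 12.7 to 1.99 CPM, as were AT3G23450 (a glycine-rich protein, 224 to 52.5), AT5G51950 (36.0 to 8.72), AT3G17050 (14.2 to 3.12) and AT5G02550 (3.88-fold lower). The salicylic acid list had a median of 0.67, above every random list, and light harvesting 0.34 (percentile 99.98), while aliphatic glucosinolate genes lay at -0.35 (percentile 0.25). In all, 337 of 14025 genes differed at least 2-fold, 238 higher and 99 lower, with no replicate check.

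On GM plates iron-deficiency, aliphatic glucosinolate and light-harvesting genes were higher in lsm8-1, each with a list median above every matched random list (2.36, 1.23 and 0.84). So were flavonoid genes (0.39) and the ABA list (0.37), with 6 of 14 and 6 of 23 members at 5 CPM or more. Root markers had a median of -0.16 there. Whether a different share of leaf and root tissue in this pair moved these lists was not tested. CYP79F1 (AT1G16410), MAM1 (AT5G23010) and CYP83A1 (AT4G13770), enzymes of aliphatic glucosinolate synthesis, went from 51.7 to 197, 167 to 490 and 214 to 561 CPM. FLC (AT5G10140, the floral repressor) went from 2.14 CPM to no read, and flowering-time genes had a median of -0.24 (percentile 4.21). The highest single genes were AT4G04170 (at least 476-fold, against the floor of 3 counts, 0.0704 CPM), AT2G01422 (0.258 to 25.3 CPM, 98.1-fold, 54.6 to 197), QQS (43.8-fold, 31.9 to 61.8), AT2G04050 (36.2-fold, 26.7 to 50.2) and AT2G18193 (35-fold, 30.1 to 40.9). The lowest was AT3G01345, at 426 CPM in Col-0 and 9.65 in lsm8-1, 44.1-fold lower. It was under 1 CPM in all soil libraries of both genotypes. MLP328 was 10.4-fold lower and its near-identical neighbour MLP329 (AT2G01530) 8.37-fold, IGMT1 (AT1G21100, an indole glucosinolate methyltransferase) 7.88-fold and AT3G58550 7.59-fold. In all, 420 of 13254 genes differed at least 2-fold, 206 higher and 214 lower, or 168 higher and 368 lower with scaling by library totals. With no change simulated, 67 genes passed 2-fold under the fitted dispersion.

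With NaCl, the flavonoid and anthocyanin list had a higher median in lsm8-1 and the ABA list a lower one. DFR (AT5G42800, dihydroflavonol reductase) stood at 19.3 CPM in Col-0 and 194 in lsm8-1, UF3GT (AT5G54060) at 8.53 and 65.3, and UGT75C1 (AT4G14090) at 20.0 and 124, the latter pair being anthocyanin sugar transferases. The list medians were 1.23 for flavonoid and anthocyanin, 1.45 for aliphatic glucosinolate, 1.42 for iron deficiency and 0.78 for light harvesting, each above every random list. They were -0.53 for ABA and osmotic stress, -0.57 for heat shock and -0.36 for cold-responsive genes, each below every random list, and 0.43 for root markers (percentile 99.6). EXT6 (AT2G24980, an extensin of the cell wall) went from 1.97 to 32.7 CPM, 16.6-fold (13.4 to 20.9). AT4G04170 was 339-fold higher (132 to 1250), AT2G01422 103-fold (58.6 to 200), QQS 61.9-fold (37.9 to 109) and SADHU3-2 23.3-fold (17.5 to 31.5). AT3G01345 was 78.0-fold lower, AT3G58550 15-fold, MLP328 7.96-fold, AT2G22590 7.40-fold and BGLU19 (AT3G21370, a beta-glucosidase that overlaps a gene on the opposite strand) 5.76-fold. In all, 567 of 13563 genes differed at least 2-fold, 382 higher and 185 lower, or 335 and 338 with scaling by library totals. The median of all genes was 0.04 at 20 °C, 0.00 on GM and 0.00 with NaCl under TMM, and 0.13, -0.12 and -0.12 with scaling by library totals. Across 12201 genes, which are not independent replicates, the log2 ratios of the genotypes correlated with r = 0.576 between 20 °C and 4 °C and 0.583 between GM and NaCl. Between experiments r was 0.172 to 0.335.

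The cold comparison asked how 24 h at 4 °C changed transcripts in both genotypes. Genes of the CBF regulon, which protects cells during freezing, rose: LTI30 (AT3G50970, a dehydrin) by 8.29 (log2, SE 0.60), KIN1 (AT5G15960) by 8.27 (SE 0.42), COR15B (AT2G42530) by 7.93 (SE 0.67) and COR15A (AT2G42540), which protects chloroplast membranes, by 7.76 (SE 0.49). Genes that fell included the cell wall expansin EXPA8 (AT2G40610, -7.70, SE 0.47), the gibberellin-regulated GASA6 (AT1G74670, -6.45, SE 0.34) and the cell wall xylosidase BXL1 (AT5G49360, -5.47, SE 0.37). These 7 genes had adjusted p of 0.00012, 5.35e-05, 0.00019, 7.99e-05, 7.38e-05, 5.42e-05 and 9.44e-05 (edgeR quasi-likelihood, Benjamini-Hochberg) and moved alike in both genotypes. The other genes that rose most were AT4G01985 (8.70), AT1G70640 (8.14), UGT78D3 (AT5G17030, a flavonol arabinosyltransferase, 7.67), DIP2 (AT5G03210, 7.60), AT4G18422 (7.27) and FKF1 (AT1G68050, a blue-light receptor of the photoperiod pathway, 7.26). Those that fell most were AT4G27450 (-7.82), PKS4 (AT5G04190, a phototropism gene, -5.78), AT3G55240 (-5.72), BZIP61 (AT3G58120, -5.42), AT1G13650 (-5.41), AT2G05160 (-5.36) and AT5G61590 (an ERF transcription factor, -4.96). In all, 3851 genes rose and 4075 fell, 7926 in sum. COR15A and COR15B are close paralogs, as are KIN1 and KIN2. COR15B, FKF1, AT4G27450, GASA6 and BZIP61 overlap genes on the opposite strand. Temperature and light changed together in this comparison.

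By list, all 17 cold-responsive genes rose with cold, also adjusted over the list alone, CBF3 (AT4G25480), a transcription factor of this regulon, by 6.26 (SE 0.29). Of the 23 ABA and osmotic stress genes 21 rose and 1 fell, and of the 14 flavonoid and anthocyanin genes 11 rose (12 adjusted over the list alone), CHS (AT5G13930, chalcone synthase) by 2.82 (SE 0.22). Of 17 clock genes 12 rose and 2 fell. PRR5 (AT5G24470) rose by 5.54 (SE 0.37), TOC1 (AT5G61380) by 2.74 (SE 0.15) and the clock-controlled RNA-binding protein gene GRP7 (AT2G21660) by 5.94 (SE 0.19). RVE8 (AT3G09600, -1.08) and CHE (AT5G08330, -1.60) fell. Of 20 light harvesting and RuBisCO genes 16 fell, such as LHCB2.3 (AT3G27690, -2.83, SE 0.42) and RBCS2B (AT5G38420, -1.73, SE 0.21), families whose members are near-identical in sequence. Of 21 splicing factor genes 10 rose and 1 fell (12 and 2 adjusted over the list alone). RS40 (AT4G25500) rose by 2.19 (SE 0.18), PRMT5 (AT4G31120, an arginine methyltransferase of spliceosome proteins) by 1.3 (SE 0.19) and STA1 by 0.92 (SE 0.18), and SCL33 (AT1G55310) fell by 1.35. These calls are edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. Camera gave these 6 lists 3.45e-22, 1.38e-11, 4.85e-07, 2.89e-07, 4.79e-06 and 0.0393, with adjusted p = 0.152, 0.505, 0.363, 0.152, 0.674 and 0.363 with an estimated correlation.

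The remaining lists did not pass camera for cold. Of 17 salicylic acid genes 2 rose and 4 fell, PR5 (AT1G75040, a thaumatin-like protein) rising by 4.40 (SE 0.57) and WRKY70 (AT3G56400) falling (-2.13, SE 0.48), with adjusted p of 0.000994 and 0.0105 (edgeR quasi-likelihood, Benjamini-Hochberg). In heat shock and chaperones 4 rose and 1 fell of 11, the latter MBF1C (AT3G24500, -2.29). Of 9 iron-deficiency genes 2 rose (IMA1, IMA2) and 5 fell, including FRO3 (AT1G23020, a ferric reductase, -3.14, SE 0.32). Flowering-time genes had 3 up and 1 down of 10, jasmonate 2 and 1 of 13, ion transport 1 and 1 of 7, root markers 2 and 1 of 8, and reference genes 2 and 2 of 9. Senescence had 2 down of 5, cell division 2 down of 10, seed markers 1 up of 2, aliphatic glucosinolate 0 of 11 and flower markers 0 of 3 (both with 0 at an unadjusted p under 0.05 and 0 by DESeq2). Fry called 9 of the 21 lists: the 6 that passed camera, heat shock (up, adjusted p = 0.0495), seed markers (up, 0.0495) and senescence (down, 0.0459). Of the intronless genes 540 rose and 634 fell.

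Both genotypes responded to cold much alike, with r = 0.938 across 12201 genes. In Col-0, 3259 of 14522 genes differed at least 2-fold (1678 higher, 1581 lower), in lsm8-1 3088 of 14767 (1619 and 1469), and the cold-responsive list had medians of 4.68 and 4.69. KIN1 was 290-fold higher in Col-0 and 326-fold in lsm8-1, LTI30 184-fold and 476-fold, COR15A 167-fold and 262-fold, and COR15B 169-fold and 296-fold. ELIP2 (AT4G14690, a chloroplast photoprotection gene, 20.6 to 3225 CPM) was the fifth in Col-0 and RD29A (AT5G52310, a stress-inducible hydrophilic protein, 51.8 to 6916 CPM) in lsm8-1. EXPA8, GASA6, AT1G13650, BXL1 and BZIP61 were the lowest in both, at -6.58, -5.71, -5.18, -5.13 and -5.02 (log2) in Col-0 and -5.97, -5.47, -5.31, -5.24 and -4.88 in lsm8-1. The response differed at least 2-fold for 209 of 15049 genes, 139 higher and 70 lower in lsm8-1. Glutathione transferases GSTU4 (AT2G29460, 2.42) and GSTU9 (AT5G62480, 2.2), the sulfotransferase SOT12 (AT2G03760, 1.94), NDB4 (2.5), AT2G04050 (1.92), AT2G32020 (2.28) and AT3G28580 (2.23) were among the most different. MO1 (AT4G15760, a monooxygenase, 2.75) went from 22.7 to 5.69 CPM in Col-0 and from 36.2 to 69.5 in lsm8-1. Lower were PDF1.2A (-2.95), which went from 1.68 to 12.7 CPM in Col-0 and from 3.51 to 1.99 in lsm8-1, AT5G51950 (-2.32), AT5G51440 (-2.30), AT4G25890 (a ribosomal P protein, -1.78), AT2G15830 (-1.68), AT1G75900 (-1.56), AT3G45160 (-1.54) and CRK6 (AT4G23140, a receptor-like kinase, -1.53). The salicylic acid list was -0.60 in Col-0 and 0.24 in lsm8-1. Its median difference of 0.47 was above every random list, and that of aliphatic glucosinolate genes (-0.51) was below every one. None of these values had a replicate check.

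The salt comparison asked how 10 h with 150 mM NaCl changed transcripts in both genotypes. All 23 genes of the ABA and osmotic stress list rose. The lipid-transfer proteins LTP4 (AT5G59310) and LTP3 (AT5G59320), neighbours close in sequence, rose by 8.37 (log2, SE 0.76) and 7.51 (SE 0.84). MYB121 (AT3G30210) rose by 8.99 (SE 0.65) and BHLH92 (AT5G43650), both stress-inducible transcription factors, by 8.54 (SE 0.58). EXPA8 fell (-4.75, SE 0.39), with the extensin-like AT1G26250 (-5.01, SE 0.44) and AT1G26240 (-5.54, SE 0.73) and HBI1 (AT2G18300, a growth-promoting bHLH factor, -4.09, SE 0.42). Their adjusted p were 0.000436, 0.00086, 0.000223, 0.000305, 0.000321, 0.000387, 0.00246 and 0.000637 (edgeR quasi-likelihood, Benjamini-Hochberg). The other highest were AT5G28520 (a jacalin-like lectin, 8.12), CWINV5 (AT3G13784, a cell wall invertase relative, 7.98), BGLU27 (AT3G60120, 7.51), DIP2 (7.48), AT5G05220 (7.42) and HSP22.0 (AT4G10250, an ER heat shock protein, 7.10). The other lowest were AT3G01260 (-6.26), GSTF14 (AT1G49860, -4.81), AT5G46900 (-4.67), AT5G46890 (-4.58), AT4G12510 (-4.36) and CRK30 (AT4G11460, -4.32). AT5G46890 and AT5G46900 are near-identical, as are AT1G26240 and AT1G26250. In all, 3068 genes rose and 3051 fell, 6119 in sum. AT5G28520 lost its call with DESeq2 (adjusted p = 0.132), and CWINV5, AT3G01260 and AT1G26250 overlap genes on the opposite strand.

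By list, all 23 ABA and osmotic stress genes rose with salt, also adjusted over the list alone, such as RAB18 (AT5G66400, a dehydrin, 6.99, SE 0.53), RD29B (AT5G52300, 6.22, SE 0.38) and NCED3 (AT3G14440, the rate-limiting enzyme of ABA synthesis, 4.66, SE 0.38). Of 17 cold-responsive genes 14 rose (15 adjusted over the list alone), of 11 heat shock genes 10, HSP70-4 (AT3G12580) by 3.44 (SE 0.29), and of 14 flavonoid genes 11 (12), PAP2 (AT1G66390, a MYB activator of anthocyanin genes) by 6.70 (SE 0.37). Of 13 jasmonate genes 7 rose, including JAZ1 (AT1G19180, a repressor of the pathway, 2.45, SE 0.18), and of 5 senescence genes 2, ORE1 (AT5G39610, 2.41, SE 0.29) and ASN1 (AT3G47340, 2.5, SE 0.48). All 9 iron-deficiency genes fell, as did 8 of 10 cell division genes (9 adjusted over the list alone), PCNA1 (AT1G07370, the DNA replication clamp) by 1.41, and 4 of 11 aliphatic glucosinolate genes. Of the 8 root markers 3 fell: IRT1 (AT4G19690, the root iron transporter, -2.86, SE 0.22), PHT1;1 (-1.43, SE 0.23) and BGLU23 (-1.27, SE 0.20). The single-gene calls are edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. Camera gave the ABA, cold, heat shock, flavonoid, jasmonate and senescence lists 3.50e-32, 2.11e-14, 1.13e-07, 4.21e-07, 6.81e-04 and 0.0182, with adjusted p = 0.204, 0.204, 0.204, 0.204, 0.204 and 0.219 with an estimated correlation. For iron deficiency, cell division, aliphatic glucosinolate and root markers it gave 1.09e-05, 7.17e-05, 0.0105 and 0.0105, with adjusted p = 0.219, 0.204, 0.798 and 0.292 with an estimated correlation.

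The other lists did not pass camera for salt. Of 7 ion transport genes 2 rose, the vacuolar sodium antiporters NHX1 (AT5G27150, 0.56, SE 0.16, adjusted p = 0.0338) and NHX2 (AT3G05030, 1.36, SE 0.20, adjusted p = 0.00236), and 2 fell, the sodium transporter HKT1 (AT4G10310, -2.64, SE 0.32, adjusted p = 0.00115) and the vacuolar pump AVP1 (AT1G15690, -0.75, SE 0.16, adjusted p = 0.00992; edgeR quasi-likelihood, Benjamini-Hochberg). SOS1 (AT2G01980, the plasma membrane antiporter) had 0.18 (SE 0.18, adjusted p = 0.495). Light harvesting had 2 up and 5 down of 20, RBCS2B falling by 3.04, clock genes 3 and 2 of 17, salicylic acid genes 5 and 1 of 17, flowering time 1 up of 10, and splicing factors 1 and 1 of 21 (0 adjusted over the list alone). Flower markers had 0 of 3 by edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2), seed markers 1 up of 2 and reference genes 1 down of 9. Fry called 10 of the 21 lists: 9 of the 10 that passed camera, without aliphatic glucosinolate, and seed markers (up, adjusted p = 0.0162). Of the intronless genes 609 rose and 490 fell.

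The salt responses of both genotypes correlated with r = 0.898 across 12201 genes. In Col-0, 2599 of 13923 genes differed at least 2-fold (1447 higher, 1152 lower), and in lsm8-1 2438 of 13822 (1488 and 950). In lsm8-1 the ABA list was less induced (median 3.10 against 3.77 in Col-0) and the flavonoid list more (2.92 against 1.95). RAB18 went from 3.90 to 938 CPM in Col-0, 241-fold, and from 6.58 to 531 in lsm8-1, 80.7-fold. LTP4 was 675-fold and 225-fold higher and LTP3 322-fold and 139-fold, in Col-0 and lsm8-1. AT2G37870 (456-fold) and LEA4-5 (AT5G06760, a late embryogenesis abundant protein, 166-fold) completed the 5 highest in Col-0, and AT3G02480 (74.8-fold) and DIP2 (89.2-fold) those in lsm8-1. The lowest in Col-0 were AT1G26250 (63.9-fold lower), FLA9 (AT1G03870, an arabinogalactan protein, 25.8-fold), IMS2 (AT5G23020, 32-fold), AT4G12520 (31.7-fold) and AT5G46900 (40.8-fold). In lsm8-1 they were EXPA8 (33.5-fold lower), AT2G27402 (17.1-fold), AT1G26250 (16.9-fold), FRO2 (AT1G01580, the root ferric reductase, 16.3-fold) and GER3 (AT5G20630, a germin-like protein, 3273 to 284 CPM).

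The difference in salt response between the genotypes was at least 2-fold for 570 of 14425 genes, 402 higher and 168 lower in lsm8-1. EXT13 (AT5G35190, an extensin, 2.79) went from 29.4 to 0.985 CPM in Col-0 and from 48.8 to 21.4 in lsm8-1, and PRP3 (AT3G62680, a proline-rich root hair protein, 2.62) from 26.0 to 1.84 and from 36.5 to 23.2. The root-marker list was at -1.55 in Col-0 and -0.48 in lsm8-1. CYP71A12 (AT2G30750, an enzyme of indole defence compounds, 3.43), AGP22 (AT5G53250, an arabinogalactan peptide, 2.74), AT3G25573 (2.71), SIB1 (AT3G56710, a defence regulator, 2.66), AT5G47980 (2.61) and AT2G15780 (2.54) were also higher. Lower were AT2G18193 (-3.18), AT2G22590 (-3.06), GolS4 (AT1G60470, galactinol synthase, -2.90), AT1G24580 (-2.35), WSD1 (AT5G37300, a wax ester synthase, -2.29), EXPA10 (AT1G26770, an expansin, -2.25), AT4G33070 (a pyruvate decarboxylase, -2.22) and AT2G37870 (-2.19). GolS4 went from 1.90 to 130 CPM in Col-0 and from 7.07 to 47.7 in lsm8-1. The median difference of the ABA list was -0.96, that of heat shock genes -0.65 and that of cold-responsive genes -0.51, each below every random list matched on expression. Flavonoid genes (0.74) and root markers (1.03) were above every one, and iron-deficiency genes had -0.45 (percentile 0.14), which turned positive with a pseudocount of 0.1 (0.26). Against random lists matched on the mean salt response, the cold-responsive list lay at percentile 3.42, inside the central 95% (-0.56 to 0.20). The ABA list lay at 0.01, where the random median was already -0.39, heat shock at 0.4, iron deficiency at 0.08, flavonoid genes at 100 and root markers at 99.98. These differences had no replicate check. RAB18 and GolS4 overlap genes on the opposite strand.

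**Figure D3:**
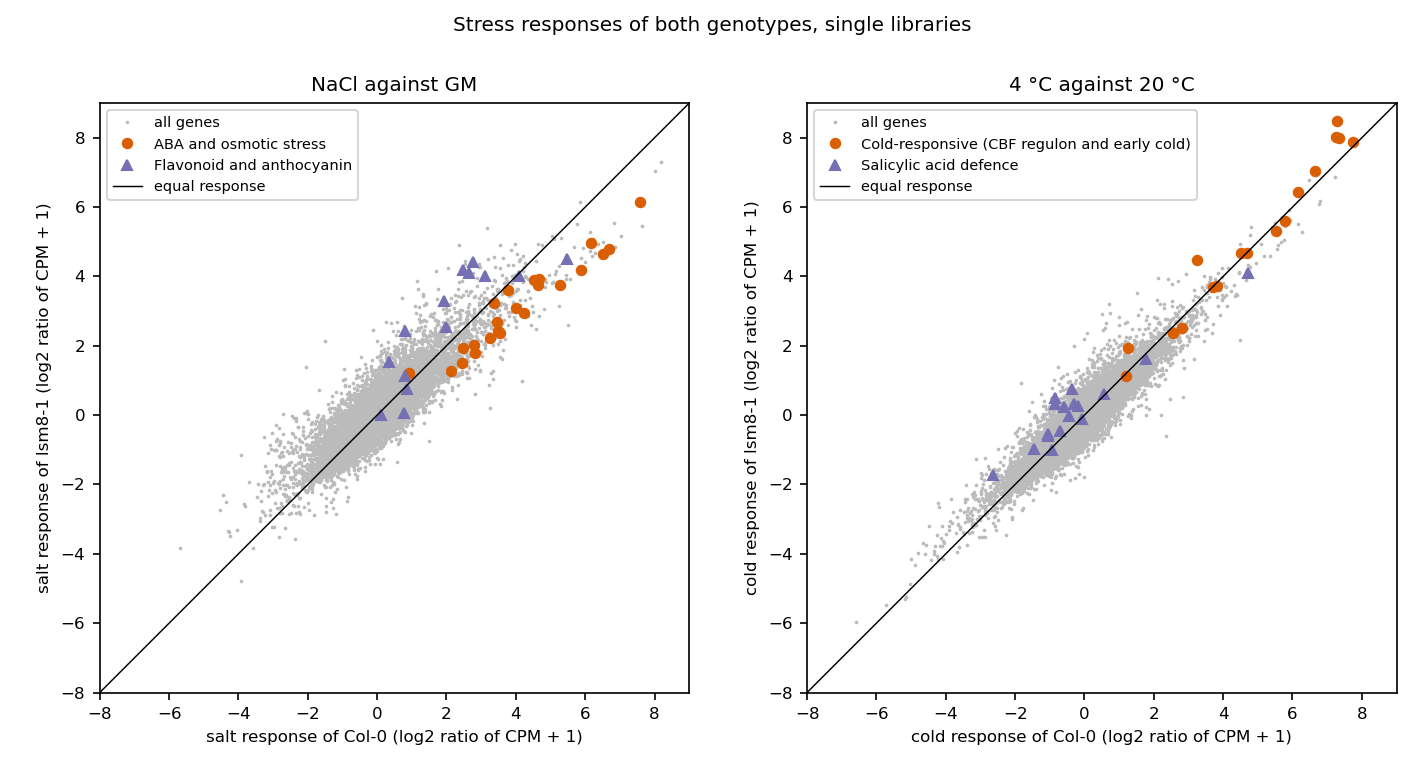
Log2 ratio of CPM + 1 in lsm8-1 (vertical) against Col-0 (horizontal), for NaCl against GM (left) and 4 °C against 20 °C (right), with 1 gene per point and the line of equal response. The ABA list has medians of 3.77 in Col-0 and 3.10 in lsm8-1, the flavonoid list 1.95 and 2.92, the cold-responsive list 4.68 and 4.69, and the salicylic acid list -0.60 and 0.24.

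**Figure D4:**
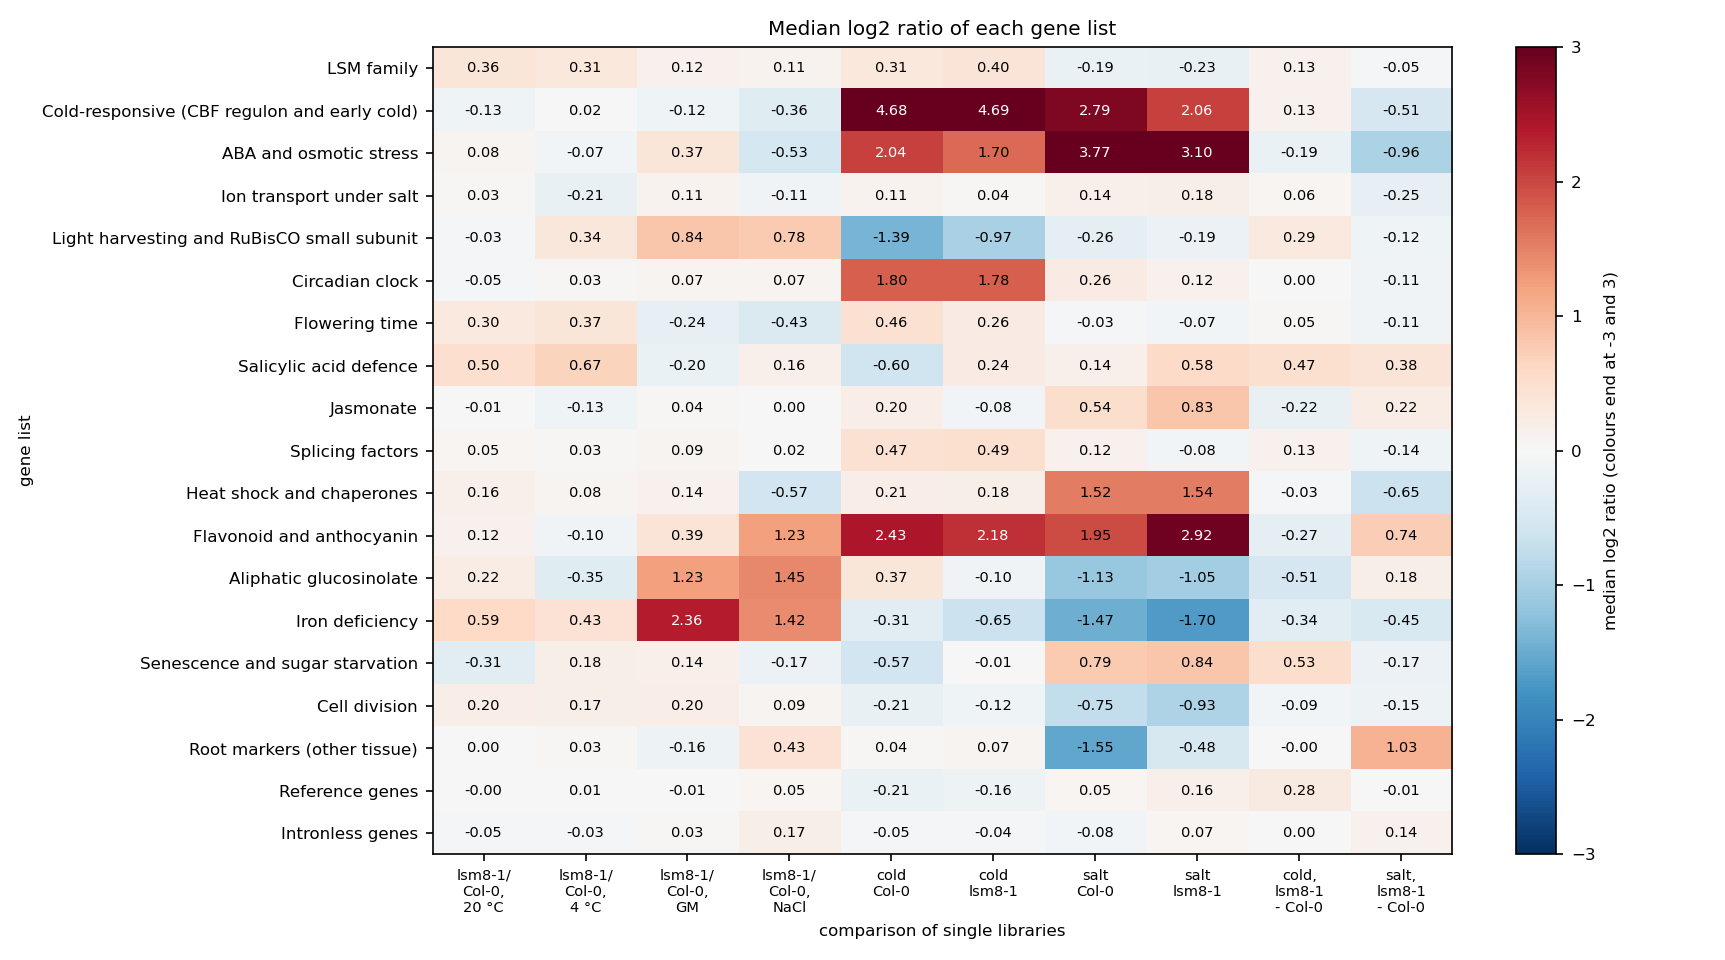
Median log2 ratio of each gene list (colour and number, colours ending at -3 and 3) in the 4 pairs of genotypes, the 4 stress responses and the 2 differences in response, from single libraries. The iron-deficiency list has 0.59, 0.43, 2.36 and 1.42 in the 4 pairs of genotypes.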

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

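The tests of explanations in this part, for the genotype count, the iron-deficiency list and the ABA list, were chosen only after the result was seen.

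Of the 8 ways of exchanging the genotype labels within the 4 pairs, the real one gave 221 genes and the highest of the others 0, so 1 split gave as many, but 8 splits are too few for a share under 0.05. The 221 genes became 29 to 101 when the pair of 1 condition was left out, in fits with fewer residual degrees of freedom.

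The iron-deficiency list was higher in lsm8-1 in all 4 pairs, most on GM. On plates the lowest median of the members at 5 CPM or more (9 on GM, 7 with NaCl) over both pairs and 3 scalings was 2.08 (log2). The scalings moved the median of all genes only from 0.00 to -0.12 in both pairs. The choice among these 3 therefore does not account for the list, and the test could hardly have failed. A member counted where either library reached 5 CPM, so lsm8-1 alone could bring it in. All 9 members had a median of 1.42 with NaCl. In soil 3 of 9 members reached 5 CPM, too few to decide (lowest median 0.28), and the other values lie near the floor. Reads lost at loci with several transcript models are argued against, since the 7 of 9 members with 1 model had a median of 2.36 on GM. More root tissue in lsm8-1 is argued against on GM, where root markers had -0.16, but stays open with NaCl, where they had 0.43 beside 1.42 for the list. A candidate explanation that stays open is a change of iron supply or signalling in lsm8-1, which may differ with the medium. It was found and tested on the same single libraries, and with the GM pair left out no member passed the edgeR test (0 of 9, all 9 at an unadjusted p under 0.05).

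The ABA and osmotic stress list differed between the genotypes by 0.37 (log2) on GM, where 6 of 23 members reached 5 CPM, and by -0.53 with NaCl, where 21 did, moving in opposite directions, a difference of -0.90 that was not tested against replicates. The list's difference in response (-0.96) lay at percentile 0.01 of random lists with a like mean response, though their median was already -0.39. Its members vary together (estimated correlation 0.50 for salt), which random lists do not copy. A smaller salt response of all induced genes in lsm8-1 is therefore argued against only weakly as the whole cause. A smaller share of leaf tissue with NaCl is argued against as the whole cause, since light-harvesting genes, which would move with it, had a difference in response of -0.12 (quartiles -0.24 and 0.07). Root markers had 1.03 there and 0.43 in the NaCl pair, so a higher share of root tissue in the lsm8-1 library with NaCl stays open as a part of it. A higher starting level on GM is argued against by the list median of -0.53 reached with NaCl. A weaker or earlier ABA response in lsm8-1 stays open as a hypothesis, as does a difference in when or how strongly the single NaCl samples met the salt, which these tables could not separate.

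The other differences below had opposite signs in the groups compared, and the difference was not tested for any of them. Flowering-time genes had a median of 0.34 (log2) over the genotype pairs of the cold experiment and -0.33 over those of the salt experiment, a difference of -0.67. Of their 10 members 6 and 7 reached 5 CPM at 20 °C and 4 °C, but 3 on GM and 3 with NaCl. The values on plates thus rest mostly on genes at low counts. The salicylic acid list had -0.60 in the cold response of Col-0 and 0.24 in that of lsm8-1, a difference of 0.84. Aliphatic glucosinolate genes had 0.22 between the genotypes at 20 °C and -0.35 at 4 °C, a difference of -0.57. Between the genotypes on GM and with NaCl, CYP71A12 had -1.61 and 1.82 (difference 3.43), AGP22 -1.21 and 1.53 (2.74), GolS4 1.48 and -1.42 (-2.90) and EXPA10 1.01 and -1.24 (-2.25).

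The share of each transcript model within its locus in the salt tables, which no comparison above uses, held a signal between the genotypes. Of 3416 loci with at least 50 reads in each library, the main model changed its share of the locus by 20 percentage points or more in 240 on GM and in 121 with NaCl. In 66 loci it did so in the same direction in both, and in 0 in opposite directions. For the salt treatment in each genotype the counts were 58 and 81, with 10 in the same direction and 1 in opposite directions. Examples, chosen after their values were seen, are SR45a.1, from 22.4% to 63.1% on GM and from 45.8% to 72.2% with NaCl (Col-0, lsm8-1), and FLM.3, from 33.3% to 70.9% and from 27.7% to 57.9%. How reads shared by models were counted is not stated, and the differences were not tested against replicates.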

How the results depend on the processing

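Tests chosen only after the result was seen are the counts on genes with 1 transcript model (13 counts within 1.5 times) and on genes with reads in both experiments (3 counts within 1.5 times). The genotype count of 221 was 1405 with DESeq2, 1504 in the cold experiment alone, 29 to 101 leaving out the pair of each condition, and 0 with no condition term (98 at an unadjusted p under 0.05, edgeR). A floor of 20 CPM, which leaves fewer genes, gave 87 (20 °C), 185 (4 °C), 209 (GM) and 306 (NaCl) genes for genotype, 2054 for cold in lsm8-1, 1532 and 1466 for salt in Col-0 and lsm8-1, and 117 and 300 for the differences in cold and salt response. A pseudocount of 0.1 gave 325 for the difference in cold response. Camera with an estimated correlation called 0 lists for genotype, 0 for cold and 0 for salt, in place of 5, 6 and 10. The iron-deficiency list's difference in salt response reversed to 0.26 with a pseudocount of 0.1. Of 200 list medians, counted apart for each setting, 47 moved by 0.1 (log2) or more with library totals (at most 0.26), 75 with a pseudocount of 0.1, the reversed one included (at most 1.80), and 0 with DESeq2 size factors (at most 0.04). The sign changed in 14, 3 and 4 in that order. Of 112 untested values of named genes, 37, 79 and 33 moved by more than their counting interval in the same order (at most 0.32, 3.28 and 0.04), with 32 differences in response that have no interval counted in each, and 0 changed sign. Except for the floor, the cause was not tested. The other counts stayed within 1.5 times under DESeq2 size factors, library totals, both filters, a floor of 1 CPM and each experiment alone. With DESeq2, its size factors, both filters, each experiment alone and a pair left out, the named tested genes kept their call and direction in 331 cases, lost the call in 57 and reversed in 0. Without a condition term every named genotype gene lost it. The settings listed for normalized values were not run, since counts were deposited. LSM8 has 29 reads in the lowest library.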

Other observations

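The test of mitochondrial stress genes below was planned after the pattern was seen but before its own values were. The test of transcript models for retained introns was also planned before its own counts were made. Its loci were not kept apart from the 66 shifted loci that led to it.

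Raw organelle reads were higher in lsm8-1 on plates, in single libraries without a replicate check. Mitochondrial genes had 7541 reads in Col-0 and 26533 in lsm8-1 on GM, and 7714 and 38424 with NaCl, of which ATMG01390 gave 14396 and 17932 in lsm8-1. Chloroplast genes had 19738 and 36508 reads on GM and 17178 and 69737 with NaCl. In soil both went the other way. At 20 °C Col-0 and lsm8-1 had 16206 and 12664 mitochondrial and 655690 and 504878 chloroplast reads. At 4 °C they had 14190 and 13756, and 493723 and 479042. Of 90 organelle genes tested by edgeR, 2 were higher and 0 lower for genotype, 8 rose and 3 fell with cold, and 1 fell with salt. Called separately, the cold and salt experiments shared 37 genes higher in lsm8-1 (642 and 109 calls), where 4.17 would be shared by independent lists of those sizes among 16790 genes, and 7 lower (771 and 24 calls, 1.1). These separate fits have fewer residual degrees of freedom than the full fit, so their calls rest on a weaker estimate of the spread.

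Nuclear genes listed for the mitochondrial retrograde response, which follows a disturbed respiratory chain, were among the genes higher in lsm8-1. Whether they report the respiratory chain in these plants was not tested. AOX1A (AT3G22370, the alternative oxidase) stood at 10.2 and 108 CPM at 20 °C, 50.9 and 240 at 4 °C, 33.5 and 278 on GM, and 206 and 653 with NaCl (Col-0, lsm8-1), with a genotype effect of 2.58 (log2, SE 0.28, adjusted p = 0.0151 by edgeR). UPOX (AT2G21640) had 3.02 (SE 0.16, adjusted p = 0.000869) and kept its call without each pair in turn, and SOT12 had 2.34 (SE 0.37, adjusted p = 0.0415). The call of AOX1A held only without the NaCl pair (0.00463), and that of SOT12 only without the 4 °C pair (0.0102). A candidate explanation is an induction of this response in lsm8-1, and 13 further members whose values had not been seen were listed to test it. The 12 that could be tested had medians of 1.44, 1.49, 0.91 and 0.87 (log2) at 20 °C, 4 °C, on GM and with NaCl, each above every matched random list, where under 0.5 in any pair would have counted against it. In that order 12, 12, 10 and 11 of them were higher. These members were listed for the same response and measured in the same libraries as the genes already seen. They were likely to move with those genes, so the test is weak evidence for the explanation. GSTU24 had -0.46 on GM and -0.34 with NaCl, and AT2G41380 had -1.03 on GM. Of these 12, 6 passed the edgeR test for genotype, among them AT2G41730 (3.09, SE 0.40, adjusted p = 0.0218), AT12CYS-2 (AT5G09570, 3.93, SE 0.44, adjusted p = 0.0154, at most 0.284 CPM in soil), CYP81D8 (AT4G37370, 2.52, SE 0.31, adjusted p = 0.0202) and ANAC013 (AT1G32870, a regulator of this response, 1.33, SE 0.21, adjusted p = 0.0415). Without the 20 °C, 4 °C, GM or NaCl pair 0, 2, 0 or 5 of them passed by the edgeR quasi-likelihood test (9, 9, 10 or 9 at an unadjusted p under 0.05), and the response may follow from the plants' state rather than from LSM8 itself, which was not tested.

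The loss of a U6 snRNA-binding complex could leave introns in transcripts, and the counts per transcript model allow a limited test of this hypothesis. Of 3951 loci with 2 models in the salt tables, 314 had both lengths equal to the reference model, and 53 with enough reads differed by an intron retained in 1 model. The retaining model held a higher share in lsm8-1 in 34 of the 52 loci that moved on GM (65.4%) and in 39 of 52 with NaCl (75%), where 50% or fewer would have counted against it. The median change was 2.24 and 1.71 percentage points, and 5 loci were up by 20 points or more against 0 down in each pair. The 127 other loci with 2 models had 51.2% and 49.2%, and the salt treatment in Col-0 and lsm8-1 gave 49.1% and 46.2% for the 53. Loci with large shifts were AT2G13975 (30.9% to 74.5% on GM, 43.5% to 69.0% with NaCl) and AT1G64430 (27.3% to 53.3%, 27.5% to 54.2%), chosen after their values were seen. Both, with AT3G13445 and AT4G31115, are among the 66 loci that led to this test. The counts at 20 points therefore repeat part of that pattern and are no separate evidence. These values are consistent with fewer introns spliced in lsm8-1, as a hypothesis from 1 library per group, on few loci, and without reads on the introns themselves.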
